A study of Mus musculus with 12 samples.

How the data were processed

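Heart ventricles of mouse embryos at E15.5 were pooled by genotype, with 3 pools of 4 pairs of ventricles for each of 4 genotypes, and polyA RNA was sequenced from a strand-specific library with single reads of 60 bases, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt, RSEM, limma and the mouse build GRCm38, without roles or order. The aligner and the annotation release are not given in the sources used here. The authors deposited 1 table of RSEM expected counts, estimated reads per gene that need not be whole because RSEM divides reads that match several genes between them. Of its values, 9.64% were not whole, and the column sums differed between libraries, so the values were not scaled for depth. Division of shared reads makes near-identical genes, such as the alpha globin pair and processed pseudogenes, uncertain.

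Columns were assigned to samples from their names: the WT columns match the titles, and the other 9 were matched by the alleles their names abbreviate (stop over flox with Cre, flox with Cre) or, for the columns called mutant, by naming neither flox nor Cre, which leaves the triple heterozygote, each with the replicate number of the title. That last step is an inference from the names, and values were not used in it. All 12 columns were used, and 0 were left out. The table held 38293 gene identifiers, of which 36345 were in GENCODE mouse release M21, which gave symbols, positions and exonic lengths on GRCm38; 15932 genes had no read in any library. Replicates are pools of different ventricles; whether pools shared litters is not stated. Pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 2.06 to 13.6), so none was counted as a duplicate.

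Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, glmQLFit and glmQLFTest, two-sided), with TMM scaling and the filterByExpr filter, which kept 13964 genes holding 99.9% of the counts. All 12 libraries entered 1 fit with 4 groups, 8 residual degrees of freedom and a common biological coefficient of variation of 0.0982. The contrasts were Mib1 mutant minus Cre control, triple heterozygote minus WT, the difference between those effects, and Cre control minus WT; p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes. Library totals were 10103548 to 22157720, and 1 read corresponds to 0.0452 to 0.0991 CPM.

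Before the data were examined, 39 gene lists with 773 entries (717 different genes, 629 of them tested) were fixed, as were the main design, most alternatives and the rule for named genes. That rule takes Mib1, Asxl3 and Apcdd1; for each genotype comparison and direction the 8 called genes with the largest fold change, a mean of at least 2 CPM and no overlap of CPM between groups, passing over predicted genes and pseudogenes; up to 4 members with the smallest p of each list with at least 2 called members; and the 5 called genes with the smallest p for the difference between effects and for the control groups. Other genes named for a list or a comparison, among them Alb, Hbb-bs, Alas2 and the Notch targets, were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 38 lists with at least 3 tested members. Beside it stand camera with the correlation estimated from the data (on log2 CPM with a prior count of 2) and fry, and counts of members called over all genes and adjusted over the list alone. No list called by camera in any of the 4 contrasts held with an estimated correlation.

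The alternatives were median-ratio size factors, leaving out erythroid genes, no filter on low counts, a filter at a mean CPM of 2, limma-voom, DESeq2 1.42.0, a fit of only the libraries compared, the replicate number as a block, the sex mix of the pools as a covariate (log2 CPM of Y-linked genes minus that of Xist, each with 1 added) and each replicate left out in turn. Leaving out the pools of 1 sex and leaving out all predicted genes, clone names and pseudogenes before the test were added after the data were seen. The procedure was tested on simulated counts for 13799 genes with a known set of changed ones per comparison. At log2 changes of 0.5, 1 and 2 it recovered 64.2%, 91% and 95.5% in the Mib1 mutant comparison, 59.7%, 88.1% and 100% in the triple heterozygote comparison, 49.3%, 92.5% and 98.5% between controls and 33.1%, 79.1% and 95.5% for the difference between effects, with 11, 5, 12 and 12 unchanged genes called. The changed genes were drawn only from those with a mean of at least 2 CPM. In the triple heterozygote comparison 170 simulated genes were called, against 3 in the real data. Fewer calls make the adjusted threshold stricter, so the simulated recovery is too high for that comparison. The same holds for the controls (172 simulated, 39 real) and the difference between effects (292 simulated, 72 real).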

Results

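Ventricles of mouse embryos at E15.5 were profiled by polyA RNA sequencing in 4 genotypes, each represented by 3 pools of 4 pairs of ventricles. The Mib1 mutant carried a premature stop allele of Mib1 over a loxP-flanked allele together with Tnnt2-Cre, a driver that recombines loxP sites in cardiomyocytes. Its control, called the Cre control here, carried 1 loxP-flanked and 1 normal Mib1 allele with the same driver. The triple heterozygote carried the Mib1 stop allele and missense alleles of Asxl3 and Apcdd1, each on 1 chromosome copy, and was set beside wild-type (WT) embryos. Mib1 encodes a ubiquitin ligase needed in ligand-presenting cells for Notch signalling, Asxl3 a partner of the Polycomb deubiquitinase BAP1, and Apcdd1 a membrane inhibitor of Wnt signalling. According to its title, the series concerns a hereditary human cardiomyopathy and the genetic basis it has in common with bicuspid aortic valve.

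The libraries held 10103548 to 22157720 estimated reads in genes, with 22157720 in triple heterozygote replicate 2 and at most 14774121 in each of the other 11. A single read was worth 0.0452 to 0.0991 CPM, the count scaled to a common library size. The first principal component, 27.2% of the variance, placed the 6 Cre control and Mib1 mutant libraries at negative scores (-29.7 to -13.1) and the 6 WT and triple heterozygote libraries at positive scores (15.2 to 23.4). Xist, transcribed from the inactive X chromosome, was near zero in Cre control replicate 1 (0.387 CPM) and Mib1 mutant replicate 1 (0.095 CPM) and lay between 71.5 and 458 CPM in the other 10 pools. Values below are means ± SD over n = 3 pools, and fold changes are on the log2 scale with their standard error (SE).

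Mib1 transcripts were lower in both genotypes that carry the stop allele. Mib1 (ENSMUSG00000024294; GRCm38 chromosome 18, 10725548 to 10818704) averaged 136 ± 9.45 CPM in WT, 68.7 ± 9.29 in the triple heterozygote, 105 ± 3.51 in the Cre control and 52.2 ± 2.41 in the Mib1 mutant (SD, n = 3 each). It fell by 1.01 (SE 0.09) in the Mib1 mutant against the Cre control, with an adjusted p of 4.75e-05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (called the edgeR adjusted p from here on). Against WT it fell by 0.99 (SE 0.09) in the triple heterozygote, at an edgeR adjusted p of 0.000276. Between the control groups Mib1 differed by -0.37 (SE 0.09), which did not pass at an edgeR adjusted p of 0.15 but did with no filter on low counts (0.0304), with DESeq2 (0.0423) and in a fit of those 6 libraries alone (0.0393). A missense allele need not alter the transcript level of its gene. Asxl3 (ENSMUSG00000045215; chromosome 18, 22344883 to 22530227) differed by -0.05 (SE 0.25) and Apcdd1 (ENSMUSG00000071847; chromosome 18, 62922231 to 62961179) by -0.04 (SE 0.18) in the triple heterozygote, at edgeR adjusted p of 0.964 and 0.961. In the Mib1 mutant Apcdd1 differed by 0.56 (SE 0.18, edgeR adjusted p 0.141), by 0.73 (edgeR adjusted p 0.0398) without Mib1 mutant replicate 1 and by 0.31, which did not pass, without replicate 2. That replicate held 19.4 CPM of Apcdd1 against 10.8 and 14 in replicates 1 and 3. Gene-level counts cannot show the deleted part of the loxP-flanked allele.

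**Figure D1:**
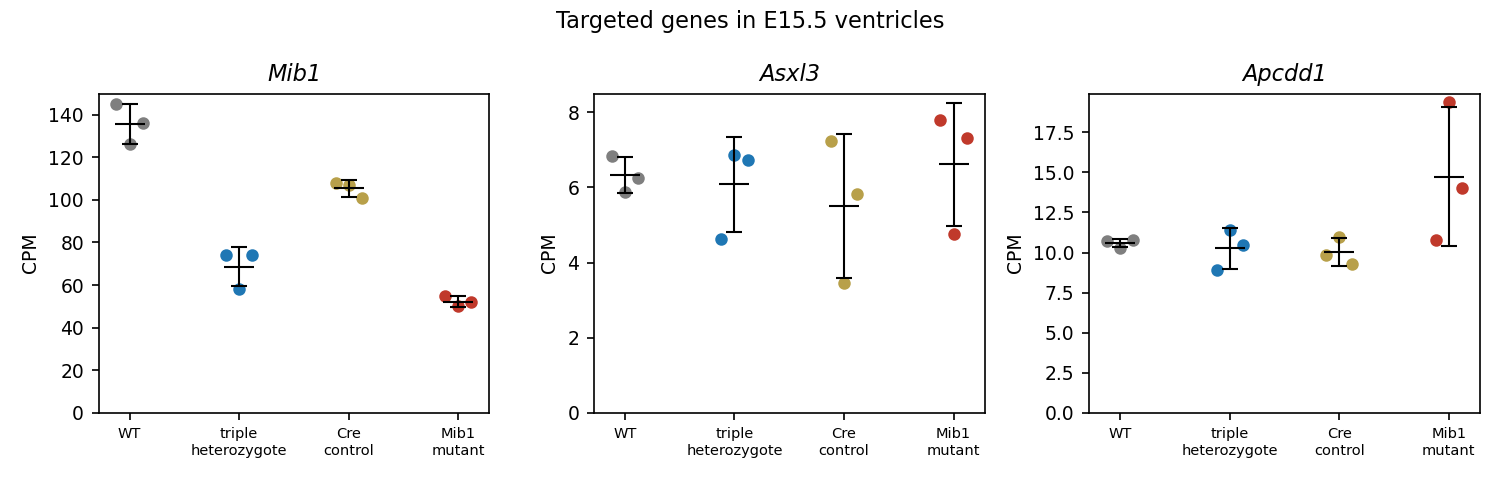
CPM of Mib1, Asxl3 and Apcdd1 in each of the 12 pools, by genotype, with the mean and SD of the 3 pools drawn as black bars. Mib1 lay at 50.1 to 54.8 CPM in the Mib1 mutant and 57.9 to 74.1 in the triple heterozygote, below the 101 to 108 of the Cre control and the 126 to 145 of WT.

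The first comparison asked how the Mib1 mutant genotype changed the ventricular transcriptome. It does not isolate loss of Mib1 in cardiomyocytes. The stop allele does not depend on Tnnt2-Cre, so other cells of the Mib1 mutant carry it too, while those of the Cre control do not. The growth factor Bmp10, which maintains the growth of trabecular cardiomyocytes, fell 6.14-fold, from 27.9 ± 8.62 CPM in the Cre control to 4.51 ± 1.89 in the Mib1 mutant (SD, n = 3). Angpt1, a ligand of the endothelial receptor Tie2, fell 4.15-fold, from 36.7 ± 6.2 to 8.86 ± 0.161 CPM. In the other direction, the T-type calcium channel gene Cacna1g rose 3.65-fold, from 22.4 ± 3.17 to 81.9 ± 6.67 CPM, and the kinesin gene Kif1a rose 3.54-fold, from 18 ± 1.87 to 64 ± 10.2 CPM. Atrial natriuretic peptide (Nppa) fell from 846 ± 38.6 to 318 ± 154 CPM, and connexin 40 (Gja5), a gap junction protein of trabecular and conducting myocardium, from 110 ± 16.3 to 47.9 ± 12 CPM.

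Of 13964 genes tested, 210 passed an edgeR adjusted p of 0.05, with 127 higher and 83 lower in the Mib1 mutant, and 20 of the higher and 31 of the lower ones changed at least 2-fold. At an unadjusted p under 0.05 there were 1954 genes, where chance gives 698. The named genes with the largest falls were Bmp10 (chromosome 6, 87428994 to 87437677, edgeR adjusted p 0.000273), Gpnmb (6.02-fold, 0.00324), Spp1, which encodes osteopontin (4.64-fold, 0.00298), Angpt1 (chromosome 15, 42424723 to 42676977, 2.64e-05), Tmem163 (3.84-fold, 0.0327), the potassium channel gene Kcnd2 (3.05-fold, 7.07e-05), Mal (3.05-fold, 0.00626) and Gtsf1 (2.97-fold, 0.000542). Those with the largest rises were Sost, a secreted Wnt antagonist (3.71-fold, edgeR adjusted p 0.0435), Cacna1g (chromosome 11, 94408391 to 94474198, 7.59e-06), Kif1a (chromosome 1, 93015464 to 93101951, 7.59e-06), Sntg2 (3.32-fold, 0.00138), Adamtsl2 (2.64-fold, 6.62e-05), elastin (Eln, 2.63-fold, 0.008), Tagln, a smooth muscle actin-binding protein (2.58-fold, 0.000179), and the deiodinase gene Dio2 (2.41-fold, 0.00458). Gpnmb and Spp1 averaged 21.5 ± 1.55 and 39.9 ± 5.51 CPM in the Cre control but 9.8 ± 4.5 and 17.3 ± 8.11 in WT (SD, n = 3). WT replicate 3, at 4.68 and 8.22 CPM, lay within the range of the Mib1 mutant pools (2.09 to 5.78 and 5.86 to 12.1). The size of their falls may thus rest in part on high Cre control values, although neither gene was called between the control groups. The count of called genes was 123 without Cre control replicate 2, 116 without Cre control replicate 3 and 415 without Mib1 mutant replicate 2. It was 110 without the pools of 1 sex (replicate 1 of both groups, left out after the data were seen), 93 in a fit of the 6 libraries alone, 476 with no filter on low counts and 417 with DESeq2. Sost rested largely on Mib1 mutant replicate 2 (7.83 CPM against 3.14 and 2.67 in replicates 1 and 3), and without it the log2 fold change of Sost was 1.25 in place of 1.89. That of Tmem163 was -2.67 without the same replicate, in place of -1.94. The edgeR adjusted p of Sost was 0.0502 to 0.159 without Cre control replicate 1, 2 or 3 or Mib1 mutant replicate 1 or 2, that of Tmem163 0.0793 to 0.141 without Cre control replicate 1, 2 or 3 or Mib1 mutant replicate 1 or 3, and that of Eln 0.0509 without Cre control replicate 2. Calls were also lost in a fit of the 6 libraries alone for Sost (0.101) and Tmem163 (0.0602), with limma-voom for Sost (0.0888), and without the pools of 1 sex for Sost (0.136), Tmem163 (0.222) and Eln (0.0615).

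**Figure D2:**
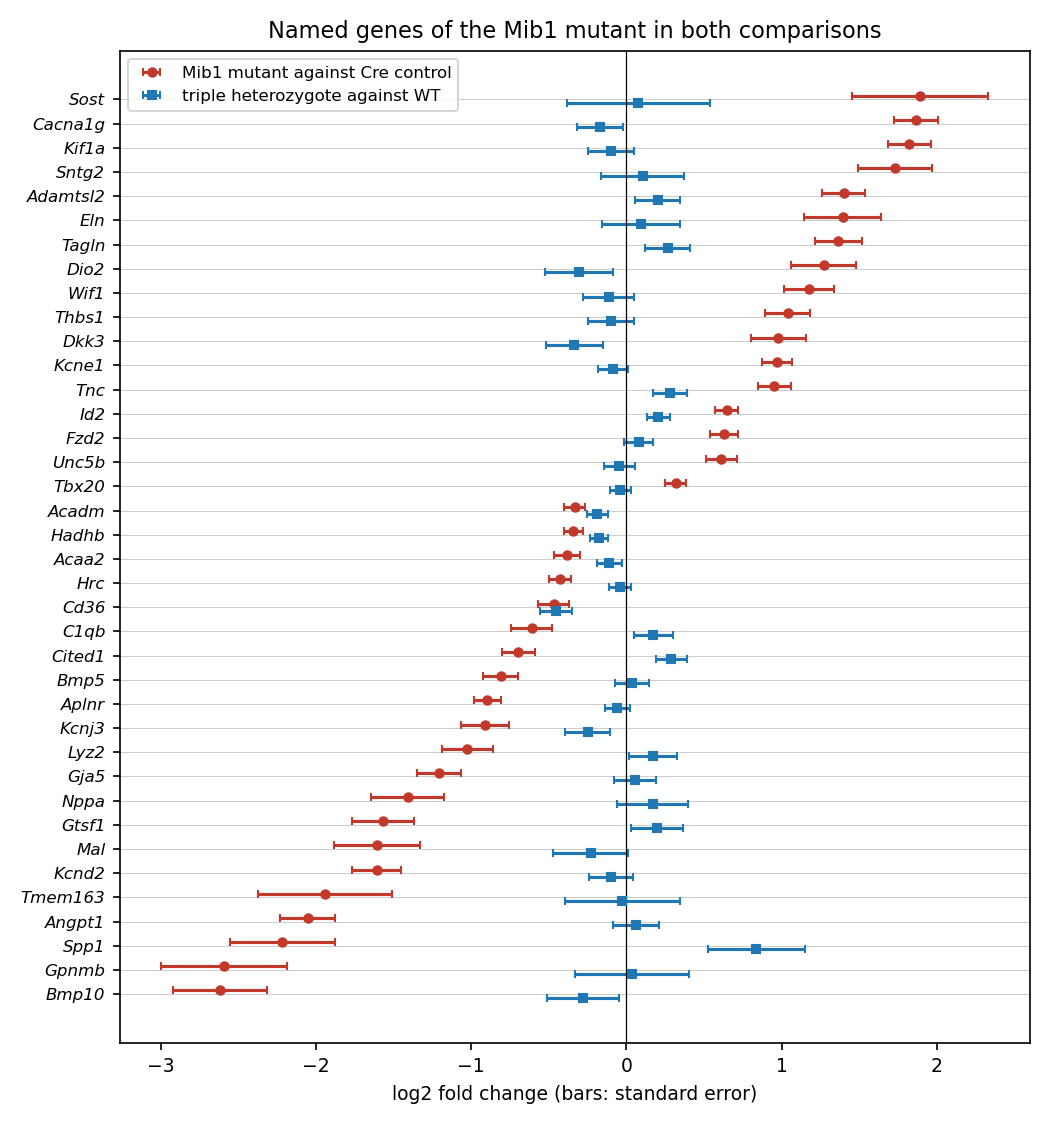
Log2 fold change with its SE for each named gene of the Mib1 mutant, in the Mib1 mutant against the Cre control (red circles) and the triple heterozygote against WT (blue squares). Bmp10 stands at -2.62 and Cacna1g at 1.87 in the Mib1 mutant, and at -0.28 and -0.17 in the triple heterozygote.

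Among 12 tested genes of trabecular myocardium, 4 fell and 1 rose. Bmp10, Gja5 (-1.21, SE 0.14), Nppa (-1.41, SE 0.23) and Cited1 (-0.69, SE 0.10) fell, at edgeR adjusted p of 0.000273, 0.000291, 0.00485 and 0.00242, while Kcne1, the beta subunit of a potassium channel, rose by 0.97 (SE 0.10, edgeR adjusted p 7.95e-05). Adjusted over the list alone, 5 were lower and 2 higher. The list lay below other genes by limma's camera (adjusted p 0.000576), a call lost at an adjusted p = 0.324 with an estimated correlation. The 15 genes of atrial myocardium held the falls of Bmp10, Nppa, Angpt1 and the potassium channel gene Kcnj3 (-0.91, SE 0.15, edgeR adjusted p 0.0059), 4 lower and 2 higher adjusted over the list alone, with a camera adjusted p of 4.87e-05 and an adjusted p = 0.485 with an estimated correlation. Its general atrial markers did not follow: Myl7 differed by 0.61 and Myl4 by -0.06, at edgeR adjusted p of 0.111 and 0.882. Of 9 genes of compact myocardium, tenascin C (Tnc; 0.95, SE 0.11) and the transcription factor gene Tbx20 (0.32, SE 0.07) rose, at edgeR adjusted p of 0.000251 and 0.0251, and both also passed when adjusted over the list alone. That list lay above other genes (camera adjusted p 0.00475, adjusted p = 0.324 with an estimated correlation). Of 13 conduction system genes, Cacna1g, Kcne1 and Id2 (0.65, SE 0.07, edgeR adjusted p 0.000273) rose and Gja5 and Cacna2d2 fell; adjusted over the list alone, 5 were higher and 2 lower. Its camera adjusted p was 1.24e-05, with an adjusted p = 0.324 with an estimated correlation. The call of Tbx20 was lost at an edgeR adjusted p of 0.0502 to 0.118 without Cre control replicate 1, 2 or 3 or Mib1 mutant replicate 1, and in a fit of the 6 libraries alone those of Tbx20 and Nppa were lost at 0.109 and 0.0562. Without the pools of 1 sex Tbx20 was at 0.112.

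Transcripts for oxidative metabolism lay lower on average in the Mib1 mutant, by small amounts and with overlap of pools in part of the lists. All 50 tested nuclear-encoded respiratory chain genes had negative values, with a median of -0.24; none passed over all genes, and 28 were lower adjusted over the list alone. Their camera adjusted p was 3.19e-20, and the adjusted p = 0.369 with an estimated correlation. The 13 mitochondrially encoded genes were all negative (median -0.29), with 12 lower adjusted over the list alone, a camera adjusted p of 5.16e-08 and an adjusted p = 0.369 with an estimated correlation. Of 26 fatty acid oxidation genes, 23 were negative (median -0.23) and 5 fell over all genes, with 16 lower adjusted over the list alone. The 5 were Hadhb (-0.34, SE 0.06), Acadm (-0.33, SE 0.07) and Acaa2 (-0.38, SE 0.08), enzymes of the beta-oxidation spiral, the fatty acid transporter Cd36 (-0.47, SE 0.10) and Cpt1b (-0.33, SE 0.08), at edgeR adjusted p of 0.00692, 0.0233, 0.0289, 0.0289 and 0.0466. That list had a camera adjusted p of 1.29e-13 and an adjusted p = 0.324 with an estimated correlation. In 30 sarcomere genes, 28 values were negative (median -0.12), none passed over all genes, and 5 were lower and 1 higher adjusted over the list alone; the camera adjusted p was 1.59e-05 and the adjusted p = 0.412 with an estimated correlation. The 52 cytosolic ribosomal protein genes had a median of -0.08 with no call over all genes or adjusted over the list alone (camera adjusted p 0.00222, adjusted p = 0.832 with an estimated correlation). Acadm lost its call at an edgeR adjusted p of 0.0671 to 0.118 without Cre control replicate 2 or 3 or Mib1 mutant replicate 1 or 3, Acaa2 at 0.0586 to 0.153 without Cre control replicate 1 or 2 or Mib1 mutant replicate 3, and Cd36 at 0.0569 to 0.117 without any 1 of the Cre control pools or Mib1 mutant replicate 2 or 3. In a fit of the 6 libraries alone Hadhb was at 0.0762, Acadm at 0.109, Acaa2 at 0.106 and Cd36 at 0.0942, and without the pools of 1 sex Acadm was at 0.0966 and Acaa2 at 0.0571. Mean log2 CPM of the respiratory chain list was 7.95 in Mib1 mutant replicate 2, above the 7.90 of Cre control replicate 1, with Cre control replicate 2 highest at 8.21. Pools also overlapped for sarcomere genes, where Mib1 mutant replicate 1 stood lowest (9.44) and replicates 2 and 3 were at 9.68 and 9.67 beside 9.67 in Cre control replicate 1, and for ribosomal protein genes (8.14 to 8.43 in the Mib1 mutant and 8.22 to 8.45 in the Cre control). They did not overlap for fatty acid oxidation (7.19 to 7.38 and 7.45 to 7.53) or mitochondrially encoded genes (11.48 to 11.73 and 11.75 to 12.05). The embryonic share of globin transcripts, which falls with age, was 1.57 ± 0.244% in the Mib1 mutant and 0.946 ± 0.457% in the Cre control (SD, n = 3), with overlap of pools (1.35 to 1.83 and 0.47 to 1.38).

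Extracellular matrix and Wnt pathway genes lay higher in the Mib1 mutant. Of 28 fibroblast and matrix genes, 27 had positive values (median 0.24); Eln (1.39, SE 0.25) and thrombospondin 1 (Thbs1; 1.04, SE 0.15) rose at edgeR adjusted p of 0.008 and 0.00155, and 11 were higher adjusted over the list alone. The list had a camera adjusted p of 4.72e-12 and an adjusted p = 0.369 with an estimated correlation. Of 20 Wnt pathway genes, the secreted inhibitor Wif1 (1.17, SE 0.16), the receptor Fzd2 (0.63, SE 0.09) and Dkk3 (0.98, SE 0.18) rose at edgeR adjusted p of 0.00132, 0.00164 and 0.00988, with 8 higher adjusted over the list alone, a camera adjusted p of 3.22e-07 and an adjusted p = 0.324 with an estimated correlation. The call of Dkk3 was lost at 0.0508 to 0.0563 without Cre control replicate 1 or Mib1 mutant replicate 1, at 0.0879 in a fit of the 6 libraries alone and at 0.155 without the pools of 1 sex, where its value was 0.64. Among 14 epicardial genes only Krt18 rose over all genes (1.19; edgeR adjusted p 0.00322), with 2 higher adjusted over the list alone, and among 12 valve mesenchyme genes only Prrx2 (0.58; 0.0429), with 2 higher and 1 lower adjusted over the list alone. Their camera adjusted p were 0.003 and 0.0041, with adjusted p = 0.493 and 0.412 with an estimated correlation. The 17 immediate early and heat shock genes had no call over all genes and 1 higher adjusted over the list alone (median 0.14, camera adjusted p 0.0267, adjusted p = 0.412 with an estimated correlation).

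Genes of the leukocyte list lay lower. Of 17 genes, 14 had negative values (median -0.52), and Lyz2 (-1.02, SE 0.17) and C1qb (-0.61, SE 0.13), expressed by macrophages, fell at edgeR adjusted p of 0.00455 and 0.0289; 8 were lower adjusted over the list alone. The camera adjusted p was 2.46e-06 and the adjusted p = 0.324 with an estimated correlation. C1qb lost its call at 0.0569 to 0.129 without Cre control replicate 2 or 3 or Mib1 mutant replicate 2 or 3, and at 0.145 in a fit of the 6 libraries alone. Among genes of the endothelial list, the apelin receptor gene Aplnr fell by 0.90 (SE 0.09, edgeR adjusted p 6.17e-05) and the netrin receptor gene Unc5b rose by 0.61 (SE 0.10, 0.00458; call lost at 0.0765 without the pools of 1 sex), while the list of 22 genes did not pass (camera adjusted p 0.529). The 3 tested liver genes were negative (median -3.05, 2 lower adjusted over the list alone; camera adjusted p 0.00804, adjusted p = 0.369 with an estimated correlation). Their level varied between single pools: Alb was at 0, 0.709 and 2.91 CPM in the Cre control pools and at most 0.186 CPM in the Mib1 mutant. The 17 genes of the noncompaction cardiomyopathy list held the fall of Mib1 and the rise of Tbx20, with 6 lower and 2 higher adjusted over the list alone (median -0.12, camera adjusted p 0.00312, adjusted p = 0.369 with an estimated correlation). That test included Mib1, which the alleles target, and was not run without it.

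The Notch lists did not pass. Mib1 was the only 1 of 30 Notch receptor, ligand and processing genes that fell (camera adjusted p 0.741), and Bmp10 the only 1 of 14 Notch target genes (0.866; the median was positive and the test negative). Hes1 differed by 0.18, Hey1 by -0.10, Hey2 by -0.04 and Heyl by 0.17, at edgeR adjusted p of 0.618, 0.845, 0.92 and 0.443. Bmp10 and Bmp5 (-0.81, SE 0.11, edgeR adjusted p 0.00138) fell among 19 trabeculation signals (camera adjusted p 0.564). In 24 calcium handling and ion channel genes Cacna1g rose and Kcnd2, Kcnj3, Kcnd3 (-1.28, SE 0.28, edgeR adjusted p 0.0289) and Hrc (-0.43, SE 0.07, 0.00486) fell (camera adjusted p 0.115); Hrc was at 0.0514 in a fit of the 6 libraries alone. The bicuspid aortic valve list held only the fall of Mib1 (camera adjusted p 0.615, with a positive median and a negative test). Camera adjusted p were 0.741 for G2/M genes, 0.119 for G1/S genes, 0.529 for p53 targets, 0.622 for glycolysis, 0.615 each for the Polycomb, endocardial and integrated stress response lists, 0.763 for Hox genes, 0.0588 for smooth muscle, 0.123 for erythroid genes, 0.909 for platelets, 0.741 for skeletal muscle, 0.973 for neurons, 0.956 for interferon response and 0.765 for sex-linked genes. In these lists, Tagln in smooth muscle and Aldoc in glycolysis (0.51; edgeR adjusted p 0.0428) were the only genes called. No lung epithelium gene was expressed highly enough to be tested.

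**Figure D3:**
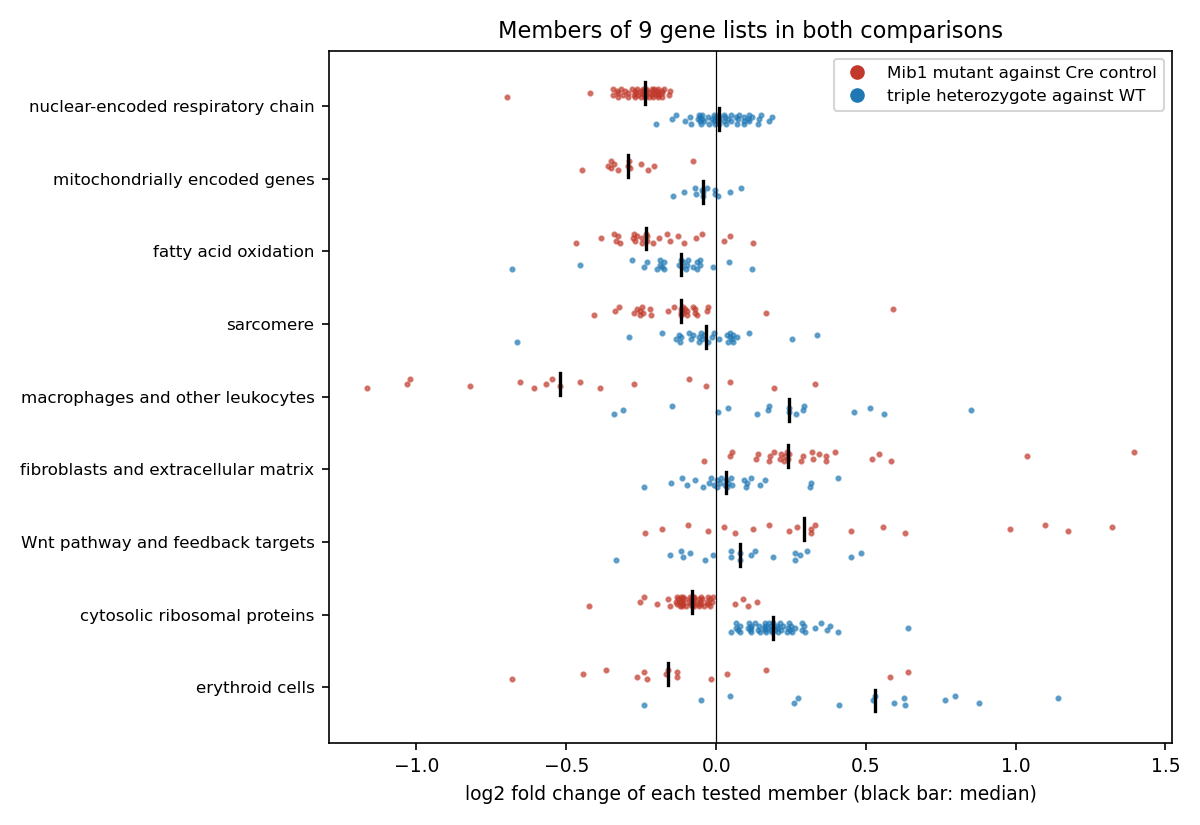
Log2 fold changes of the tested members of 9 gene lists (points) with the median of each list (black bars), in the Mib1 mutant against the Cre control (red) and the triple heterozygote against WT (blue). The respiratory chain median is -0.24 in the Mib1 mutant and 0.01 in the triple heterozygote, and the erythroid median is -0.16 and 0.53.

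The second comparison asked how heterozygosity for the Mib1, Asxl3 and Apcdd1 alleles changed the ventricular transcriptome. Apart from Mib1 itself, the genes that changed encode the alpha chains of adult haemoglobin. Hba-a1 (chromosome 11, 32283511 to 32284465) rose from 1580 ± 123 CPM in WT to 2690 ± 320 in the triple heterozygote (0.76, SE 0.11), and Hba-a2 (chromosome 11, 32296489 to 32297298) from 486 ± 36.3 to 844 ± 104 (0.80, SE 0.11, SD, n = 3). The beta chain genes Hbb-bs and Hbb-bt had values of 0.63 each that did not pass, at edgeR adjusted p of 0.0672 and 0.161. Alas2, the erythroid enzyme that starts haem synthesis, differed by 0.53 (edgeR adjusted p 0.326).

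These 3 genes, Hba-a2 (edgeR adjusted p 0.0189), Hba-a1 (0.0351) and Mib1, were the only ones of 13964 past an edgeR adjusted p of 0.05. At an unadjusted p under 0.05 there were 1209 genes, where chance gives 698, and DESeq2 called 28, limma-voom 3, no filter on low counts 54 and a fit of the 6 libraries alone 10. Hba-a1 and Hba-a2 are near-identical copies, so how reads were split between them is uncertain. Hba-a2 lost its call without triple heterozygote replicate 2 or WT replicate 1, 2 or 3 (edgeR adjusted p 0.071 to 0.204), and Hba-a1 without triple heterozygote replicate 2 or 3 or WT replicate 1, 2 or 3 (0.0901 to 0.398); 1 gene remained without each WT pool. With the replicate number as a block, Hba-a1 was at 0.0564.

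**Figure D4:**
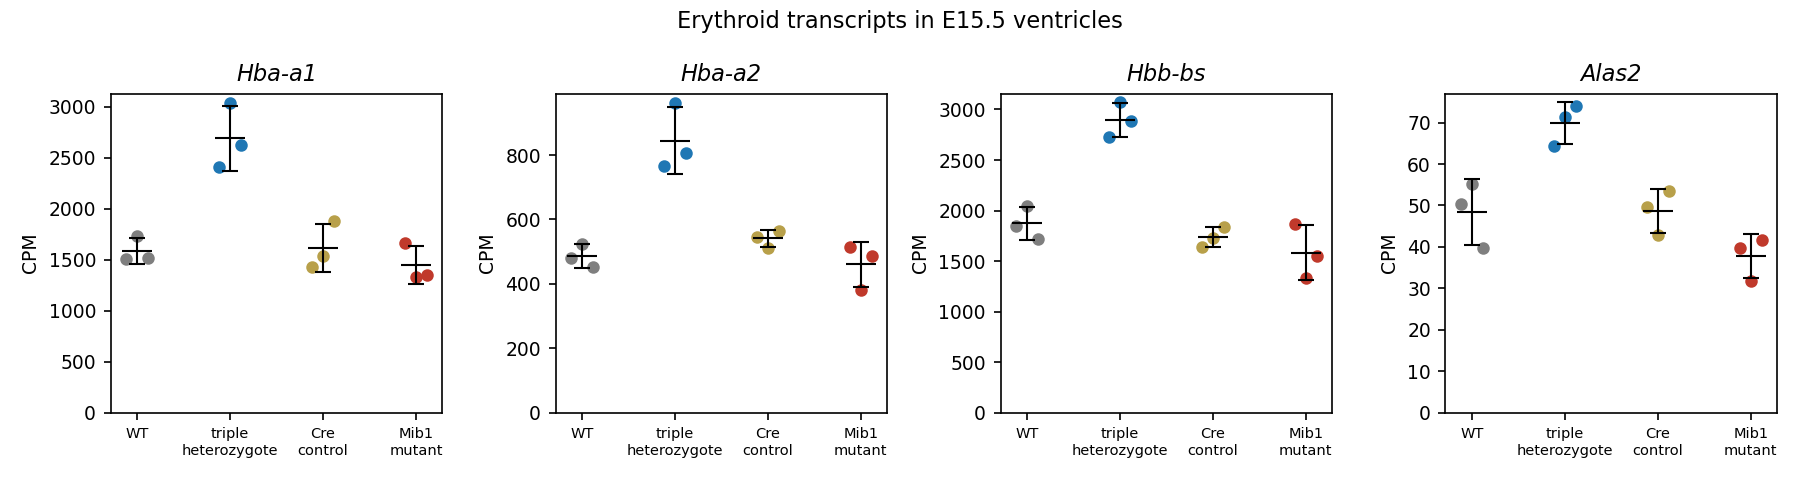
CPM of Hba-a1, Hba-a2, Hbb-bs and Alas2 in each pool, by genotype, with the mean and SD of the 3 pools as black bars. For Hba-a1 the triple heterozygote pools lie at 2410 to 3040 CPM, above the WT pools at 1510 to 1730, the Cre control at 1430 to 1880 and the Mib1 mutant at 1330 to 1660.

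Of 15 tested erythroid genes, 13 had positive values in the triple heterozygote (median 0.53), 2 rose over all genes and 7 were higher adjusted over the list alone. The camera adjusted p was 4.5e-15 and the adjusted p = 0.347 with an estimated correlation. All 52 cytosolic ribosomal protein genes were positive (median 0.19), with 2 higher adjusted over the list alone, a camera adjusted p of 2.76e-20 and an adjusted p = 0.559 with an estimated correlation. Lists higher by camera without any called gene, over all genes or adjusted over the list alone, were G1/S and DNA replication (median 0.15, camera adjusted p 4.62e-05, adjusted p = 0.733 with an estimated correlation) and leukocytes (median 0.24, 0.0167, adjusted p = 0.638 with an estimated correlation). The same held for endocardium (median 0.12, 0.0324, adjusted p = 0.347 with an estimated correlation) and the integrated stress response (median 0.06, 0.0374, adjusted p = 0.547 with an estimated correlation).

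Fatty acid oxidation genes lay lower in the triple heterozygote too, with 24 of 26 negative and a median of -0.12. None passed over all genes and 1 was lower adjusted over the list alone (camera adjusted p 4.65e-08, adjusted p = 0.347 with an estimated correlation). Calcium handling and ion channel genes were negative in 21 of 24 cases with no called gene (median -0.15, camera adjusted p 0.000117, adjusted p = 0.337 with an estimated correlation). The noncompaction list (median -0.04, 0.00789, adjusted p = 0.547 with an estimated correlation) held only the fall of Mib1, over all genes and adjusted over the list alone. Its test included Mib1, the gene with the stop allele, and was not run without it. The 3 liver genes (median -4.83, 2 lower adjusted over the list alone; 0.00168, adjusted p = 0.488 with an estimated correlation) followed Alb, at 0.822 to 9.6 CPM in the WT pools and at most 0.099 in the triple heterozygote. The other 28 tested lists had camera adjusted p of 0.137 to 0.931, among them Notch receptors (0.302), Notch targets (0.291), trabecular myocardium (0.704), compact myocardium (0.417), respiratory chain (0.794), Wnt (0.329), Polycomb (0.199) and bicuspid aortic valve genes (0.31). In 4 of these lists, compact myocardium, p53 targets, glycolysis and smooth muscle, the median and the test had opposite signs. The number of lists called rose from 10 to 17 without triple heterozygote replicate 2.

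The effects of the genotypes differed. Cacna1g rose in the Mib1 mutant and differed by -0.17 in the triple heterozygote, a difference between the effects of 2.04 (SE 0.20, edgeR adjusted p 0.000711). By that edgeR test of the difference, the effect was likewise higher in the Mib1 mutant than in the triple heterozygote for Kif1a (difference 1.92, SE 0.20, 0.00082), Plekha6 (0.95, SE 0.12, 0.00301) and Kcne1 (1.06, SE 0.14, 0.00476). For Angpt1 it was lower (-2.11, SE 0.23, edgeR adjusted p 0.000824). Bmp10 (-2.34), Gja5 (-1.26), Nppa (-1.58) and Wif1 (1.29) also differed, at edgeR adjusted p of 0.0136, 0.00815, 0.0455 and 0.0217. The haemoglobin genes Hba-a2 and Hba-a1 differed by -1.03 and -0.93 (edgeR adjusted p 0.00659 and 0.0184).

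In total 72 genes differed between the effects at an edgeR adjusted p under 0.05, and 60 of them were among the 210. The log2 fold change of the Mib1 mutant was above that of the triple heterozygote for 45 and below it for 27. The fall of Mib1 did not differ (difference -0.02, SE 0.13, edgeR adjusted p 0.954), and it was the only gene called in both comparisons. Without single pools the count was 43 (Cre control replicate 2), 38 (Cre control 3), 233 (Mib1 mutant 2), 41 (Mib1 mutant 3), 33 (triple heterozygote 1), 28 (triple heterozygote 2), 36 (WT 1), 31 (WT 2) and 32 (WT 3). Of the 38 lists, 12 differed by camera, and none did with an estimated correlation, where the lowest adjusted p = 0.695. The lower lists were the respiratory chain, mitochondrially encoded, ribosomal, G1/S, sarcomere, trabecular, atrial, erythroid and leukocyte genes, and the higher ones matrix, Wnt and conduction system genes.

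Across the 13964 genes the fold changes of both comparisons, which share no library, had a Spearman correlation of -0.114, a Pearson correlation of -0.00681 and a covariance of -0.000956; genes are not independent replicates. The Spearman value was -0.0123 without Cre control replicate 2, -0.0276, -0.201 and -0.0486 without Mib1 mutant replicate 1, 2 or 3, and -0.0496 without triple heterozygote replicate 1. Of the 210 genes called in the Mib1 mutant, 105 had the same sign in the triple heterozygote. At an unadjusted p under 0.05, 72 genes were lower in both where independent lists give 44.9 (Fisher's exact test, p = 6.69e-05), 32 were higher in both against 39.2 (Fisher's exact test, p = 0.27), 73 were higher in the Mib1 mutant and lower in the triple heterozygote against 49.7 (Fisher's exact test, p = 0.000839), and 40 went the opposite way against 35.4 (Fisher's exact test, p = 0.424). Fisher's test treats genes as independent, which they are not, so these p-values do not measure chance for the overlaps. No shared response can be read from them.

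The control groups were compared to see what separates the pairs of genotypes. This contrast is not free of Mib1 itself, because the Cre control carries a loxP-flanked Mib1 allele with Tnnt2-Cre and WT does not. The band 4.1 family gene Epb41l4a rose from 11.3 ± 0.725 CPM in WT to 31 ± 0.985 in the Cre control (1.46, SE 0.09, edgeR adjusted p 1.05e-06; SD, n = 3).

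Between Cre control and WT 39 genes passed an edgeR adjusted p of 0.05, 35 higher and 4 lower in the Cre control, and 24 of them were predicted genes or pseudogenes. The other 4 with the smallest p were of that uncertain kind: Gm10260 (33.2 CPM in the Cre control and 0.0281 in WT), Gm4735 (47.3 and 0.0822), Rps2-ps13 (76.9 and 0) and Gm6436 (19.5 and 0). Counting can divide the reads of such copies with near-identical genes elsewhere. The count was 23 without WT replicate 1 and 25 without WT replicate 2, and 144 with no filter on low counts, 82 with DESeq2 and 68 in a fit of the 6 libraries alone. Camera called 3 lists, ribosomal proteins (adjusted p 0.0148), ion channels (0.0272) and smooth muscle (0.0478), none with an estimated correlation (lowest adjusted p = 0.566 with an estimated correlation).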

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

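Of the tests in this part, the sex mix and the matrix list against the leukocyte list were chosen only after the result was seen. So were the values of the other cell lists.

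The effects of the genotypes differed by a test of the difference itself, which is what drew attention to them. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 72 genes differed, and the 5 with the smallest p were Cacna1g (difference of log2 effects 2.04), Kif1a (1.92), Angpt1 (-2.11), Plekha6 (0.95) and Kcne1 (1.06). Of 100 splits drawn for the 12 libraries, the real one included, 2 gave as many genes, with 72 in the real split and 81 in the highest other. These splits cannot exclude chance for a difference between the effects, because 90 of them mixed Mib1 mutant with Cre control, which removes the Mib1 effect, and gave 0 to 1 genes. The 9 others that kept those groups apart gave 18 to 81 genes, and adding the effects in place of subtracting them, a split not among those drawn, gave 81. The number of genes rests largely on the Mib1 mutant and says little about the triple heterozygote.

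In the Mib1 mutant, 210 genes were called, respiratory chain transcripts lay lower on average and matrix transcripts higher. By fry neither of those lists passed (adjusted p 0.0998 and 0.0957). The 9 lists that did by fry included trabecular myocardium (adjusted p 0.00446), fatty acid oxidation (0.00662) and smooth muscle (0.0234), the last not called by camera. The tables argue against the sex mix of the pools, since 201 of the 210 genes were called again with it as a covariate, although leaving out the pools of 1 sex, which also removes replicates, called 110 genes with 95 of the 210 among them. For the respiratory chain list they argue against transcript length and GC content as the whole source. Its median was -0.238, while random lists matched on length, GC and level lay at -0.154 to 0 around -0.069, with 0 of 10000 as low. Those lists hold unrelated genes, whereas members of this list vary together (estimated correlation 0.727). The 0 of 10000 is therefore no measure of chance for the list, and for the 210 genes length and GC were not tested. A smaller share of cardiomyocytes would raise the lists of all other cell types alike. The change of the matrix list exceeded that of the leukocyte list by 0.75 (log2, pooled SD 0.12). Both lists were picked after they had been seen to move in opposite directions. This test could therefore not have come out otherwise, and it decides nothing. The other lists of heart cells changed unevenly in mean log2 CPM: endothelium by -0.03, endocardium and smooth muscle by 0.07 each, epicardium by 0.24 and valve mesenchyme by 0.44. Sequence around Mib1 carried along with the alleles stays open, with 8 called genes on chromosome 18 against 5.34 by chance (Fisher's exact test, p = 0.261). So do a difference in stage, a smaller share of cardiomyocytes and a change of the share of single other cell types. A response to loss of Mib1 in cardiomyocytes is a hypothesis that these data may fit and do not single out. They cannot separate it from an effect of the stop allele in other cells.

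Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split of Mib1 mutant and Cre control called 210 genes and the highest other 2, and for gene lists called by camera the values were 17 and 15. For triple heterozygote and WT the real split called 3 genes and the highest other 0, and for lists 10 and 11. Between Cre control and WT the real split called 39 genes and the highest other 0.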

How the results depend on the processing

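The alternatives that left out pools of 1 sex and that left out predicted genes, clone names and pseudogenes were chosen after the data were seen. Of the genes named by the rule and called, 26 of 39 in the Mib1 mutant, 1 of 3 in the triple heterozygote (Mib1), 5 of 5 for the difference between effects and 5 of 5 between controls kept their call under every alternative run. By value, 610 of 663 in the Mib1 mutant and 36 of 46 in the triple heterozygote kept the call and the others lost it. No called gene among these changed sign, while Asxl3 and Apcdd1, not called in the triple heterozygote, did without single pools. Of called lists, 247 of 288 values in the Mib1 mutant and 126 of 158 in the triple heterozygote kept the call, and the others lost it. Median-ratio size factors and leaving out erythroid genes moved the median of all genes by at most 0.009 in size (-0.009 to 0.004). The 210 genes of the Mib1 mutant became 476 with no filter on low counts, 417 with DESeq2, 93 with only the libraries compared and 110 with pools of 1 sex left out, and 116 to 415 without single replicates. The 3 genes of the triple heterozygote became 1 with erythroid genes left out (by construction), 54 with no filter, 28 with DESeq2, 10 with only the libraries compared, 5 with the sex mix as covariate, 6 with predicted genes and pseudogenes left out, and 1 to 3 without single replicates. The 72 genes of the difference became 246 with no filter, 167 with DESeq2, 41 with pools of 1 sex left out, and 28 to 233 without single replicates. The 39 genes between controls became 144 with no filter, 82 with DESeq2, 68 with only the libraries compared, 15 with predicted genes and pseudogenes left out (by construction), and 23 to 42 without single replicates. The correlation of -0.114 became -0.0418 with no filter and -0.201 to -0.0123 without single replicates. Apcdd1 in the Mib1 mutant ranged from 0.31 to 0.73 without single replicates. The 17 and 10 lists called became 0 and 0 with an estimated correlation and 9 and 0 with fry, and 15 to 20 and 7 to 17 without single replicates. Except where stated, the cause was not tested. DESeq2 has no list test here.

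With the replicate number as a block (replicate block), 318 genes were called in the Mib1 mutant, 3 in the triple heterozygote, 109 for the difference and 59 between controls. Deviations of libraries with the same number correlated at 0.13, 0.17 and 0.01 for Mib1 mutant and Cre control and 0.09, -0.01 and -0.06 for triple heterozygote and WT. Not every library correlated best with its own number, so the numbers were not taken as pairs.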

Other observations

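The tests in this part, of red cells, younger embryos, near-identical copies and shared background, and the values for ribosomal lists and for length in the difference between effects, were chosen only after the result was seen.

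Further genes, chosen after their values were seen, changed in the Mib1 mutant. The serine protease gene Htra1 rose by 1.09, thrombospondin 4 (Thbs4) by 1.08 and the guidance receptor Robo1 by 1.03, at edgeR adjusted p of 0.000285, 5.43e-05 and 0.000287. Etv5 and Spry4, which respond to growth factor signalling through ERK, rose by 0.99 and 0.42 (edgeR adjusted p 0.000388 and 0.0358). The potassium channel gene Kcnk3 fell by 0.91 and glutathione peroxidase 3 (Gpx3) by 0.72 (edgeR adjusted p 0.000641 and 0.00138). Each of these 7 genes also differed between the effects of the genotypes, at edgeR adjusted p of 0.00509 to 0.0257.

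Fold changes followed transcript length across 13800 genes, which are not independent. Their Spearman correlation with exonic length was 0.231 in the Mib1 mutant and -0.349 in the triple heterozygote, and with GC content -0.0115 and 0.369. For the difference between effects the values were 0.375 and -0.231, and for Cre control against WT -0.27 and 0.238. The ribosomal protein median in the Mib1 mutant (-0.081) was met or passed by 2794 of 10000 random lists matched on length, GC and level, and that in the triple heterozygote (0.188) by 0. In the difference between effects 6, 0 and 0 such lists lay as low as the respiratory chain (-0.251), ribosomal (-0.284) and G1/S (-0.225) medians, but matched lists for the respiratory chain and ribosomal genes were themselves at a median of -0.152 and -0.148. Between the control groups 0 lay as high as the ribosomal median (0.088). Matched lists hold unrelated genes, whereas members of the respiratory chain, ribosomal and G1/S lists vary together (estimated correlation 0.727, 0.731 and 0.72). These counts of random lists are therefore no measure of chance for any of the 3 lists.

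Haemoglobin transcripts were higher in every triple heterozygote pool than in every WT pool, with summed globin CPM of 7630 ± 621 and 4710 ± 376 (SD, n = 3). More red blood cells in the pools is a candidate explanation that stays open: the erythroid genes that are not globins had a median of 0.27 against 0.76 for globins, and 6 of 8 were positive. Younger embryos could also raise globins, and stay open: the embryonic share of globin transcripts differed by 0.12 percentage points, between 0.721 ± 0.154 and 0.841 ± 0.151 (SD, n = 3), with overlapping pools. An effect of the genotype on blood content is a hypothesis these data do not separate from dissection or bleeding of the tissue.

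Of the 39 genes called between Cre control and WT, pseudogenes may take reads from their parent genes. In 4 pairs of a copy and its parent the log2 difference of their sum was -0.08 to 0.15, with a median of 0.06. A level parent would give 0.26. The gap was judged against 0.06, the mean edgeR SE of the 4 parent genes divided by 2, which is not an SE of that median. A sum below that of a level parent is what divided reads predict. The calls of these 4 copies are thus a candidate artifact of counting over a sequence difference between the lines. For the other called genes this was not tested. A background or handling shared by both Cre groups stays open because it is confounded with the genotypes: 33 of the 39 genes differed the same way between Mib1 mutant and triple heterozygote at an unadjusted p under 0.05.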
